A study of Mus musculus with 48 samples.

How the data were processed

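Gene expression was measured by RNA-seq in primary mouse embryonic fibroblasts (MEFs) of 2 genotypes, wild type (WT) and Cry2 knockout (KO), taken from littermate embryos. Dexamethasone, a synthetic glucocorticoid that sets the phase of cellular clocks, was given to synchronise the cultures. The 48 libraries fall into 12 groups, 2 genotypes at 6 times (0, 4, 8, 12, 16 and 20 h after dexamethasone), with 4 libraries numbered 1 to 4 in each. Per the labels' protocols, RNA was extracted with Trizol, ribosomal RNA was depleted with Ribo-Zero and libraries were made with the NEBNext Ultra kit, which does not mark strand. Reads from a gene and from an overlapping or antisense neighbour can therefore not be told apart.

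Per the submitters' processing notes, cutadapt 1.3, TopHat2 2.0.13, Bowtie2 and the mm10 build were used, while the program that counted reads per gene is not given in the sources used here. The deposited table of estimated counts per gene held 24060 entries, and 14.9% of its values above 0 were not whole (tolerance 1e-06), so they were rounded to whole numbers before any test. The deposited RPKM table, a length- and depth-normalised unit computed by the authors, held the same entries. Its values equalled the estimated counts divided by 1 constant per gene and 1 per library, with a median absolute residual of 4.2e-06 on the log2 scale. In 27 entries the gene symbol had been turned into a calendar date; 17 of these were tested, and none is named. Every column of values was matched to its library by title. Gene positions were taken from the RefSeq annotation of GRCm38.p6, the assembly that mm10 names, where 22600 of 24058 symbols matched by current symbol and 1279 by synonym. GC content was that of the longest GENCODE transcript of each gene.

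Library totals ran from 2496885 counts (WT 0 h replicate 4) to 10132983 (KO 12 h replicate 4), with a median of 6197478. Normalised read counts (CPM, relative to the library total) were scaled by edgeR's trimmed mean of M-values (TMM). Of 18733 genes with at least 1 count, 11743 passed edgeR's expression filter on the 12 groups and were tested. A negative binomial model with 1 mean per group was fitted to all 48 libraries in edgeR 4.0.16 (R 4.3.3), and contrasts were tested with its quasi-likelihood F-test with robust shrinkage. All adjusted p-values for genes come from this test with Benjamini-Hochberg adjustment over the tested genes, and a gene was called below 0.05. Fold changes are log2 with standard errors (SE), and levels are mean CPM ± SD. Spread was estimated from the 4 libraries of each group. The labels do not say whether these came from separate cultures or embryos, nor how many embryos gave each genotype, so p-values measure only the spread between these libraries, which may be technical.

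The comparisons were KO against WT averaged over the 6 times and at each time, change across times within each genotype, the genotype by time interaction, and 4 h against 0 h within each genotype. A rhythm was fitted as a cosine and sine with a period of 24 h in each genotype, and the difference between the rhythms was tested. Amplitude is the fitted log2 distance from mean to peak. The sampling covered 20 h, less than 1 period, so a change after 0 h that is not rhythmic can also pass. For tests across times, the size given is the log2 range of the group means (for the interaction, the range over times of the KO against WT log2 fold change).

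Design, lists and naming rule were fixed before the data were examined. Named genes are Cry2, the 10 higher and 10 lower genes of largest fold change averaged over times (adjusted p under 0.05, mean log2 CPM of at least 2, 1 direction at all 6 times, no predicted-gene symbol), 3 per direction at each time, the 10 of smallest p in each test across times, 8 per direction for 4 h against 0 h, 3 members per list and direction, and all members of the clock and MYC network lists. Of 31 gene lists written, 28 had at least 2 measured members. They cover the clock, clock genes with E-box or D-box promoters, the MYC network, MYC targets, ribosomal proteins, S phase, mitosis, replication-dependent histones, p53 targets, glucocorticoid targets, extracellular matrix, contractile genes, immediate early genes, interferon and inflammatory genes, cholesterol synthesis, glycolysis, the respiratory chain, antioxidant genes, the unfolded protein and integrated stress response, inhibitors of cyclin-dependent kinases, nuclear RNAs and positional genes. Others hold markers of endothelium, skeletal muscle, nerve, cartilage and bone, fat, epithelium, blood and macrophages, and sex-linked genes. Lists were compared with other genes by camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the 28 lists. The test was repeated with an estimated correlation, and fry, which asks only whether a list's genes move 1 way, was run beside it.

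Alternatives were DESeq2 size factors, DESeq2 1.42.0 as the test, other filters on low counts, leaving out each replicate number or single library, a replicate block, fits to part of the libraries, counts summed per genotype and number, voom with a random effect, and limma on log2(RPKM + 1) or log2(RPKM + 0.1). The RPKM values were used without TMM scaling. Matching libraries by number was tried as a block only. A fit without KO 4 h replicate 4 was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

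The scripts were tested on simulated counts with 200 changed genes. For KO against WT averaged over times, 97.0% of genes changed 1.5-fold were recovered, with 7 false calls among 11584 genes. At 4 h alone, 52.2% of 1.5-fold, 82.1% of 2-fold and 90.9% of 4-fold changes were recovered (9 false calls), and for KO 4 h against 0 h 61.2%, 77.6% and 95.5% (6 false calls among 11579 genes). For the interaction these shares were 20.9%, 61.2% and 86.4% (2 false calls). For the KO rhythm, by fold from trough to peak, they were 55.2%, 94.0% and 100.0% (11 false calls among 11564 genes), and for the difference of rhythms 34.3%, 77.6% and 93.9% (8 false calls). Camera called a simulated list of 50 genes shifted by 0.4 (log2) and 0 of 30 unshifted lists. Genes were simulated independently of each other, most of them unchanged, and without a library that stands apart. In the data 75.6% of genes differed between KO and WT averaged over times, and the estimated correlation of the histone list was 0.81. The simulated shares and false calls therefore do not show how the tests behave under those conditions. For genes with 0 to 3 counts in a genotype, a ratio has a 95% exact binomial interval, or a lower bound with a floor of 3 counts over the 24 libraries. Such intervals and floors cover counting error only.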

Results

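Cry2 encodes cryptochrome 2, a repressor in the mammalian circadian clock, and the series asks how its loss alters transcripts over a day in cells synchronised with dexamethasone, with MYC, an oncogenic transcription factor, as a main interest. RNA-seq libraries came from primary mouse embryonic fibroblasts (MEFs) of WT and Cry2 knockout (KO) littermate embryos. Each genotype was sampled at 0, 4, 8, 12, 16 and 20 h after dexamethasone, with 4 libraries per genotype and time, 48 in all. Total counts ran from 2496885 to 10132983 per library, with a median of 6455628 in WT and 6149800 in KO. Between 12725 and 14180 genes had a count in a library. All KO libraries come from the KO line or lines and all WT libraries from the WT line or lines, so the effect of Cry2 and any other difference between the embryos cannot be separated in these comparisons.

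The libraries separated by genotype. The first principal component of log2 CPM held 56.1% of the variance, with WT libraries between 40.6 and 53.4 and KO libraries other than KO 4 h replicate 4 between -53.3 and -44.7. Without that library it held 65.8%. KO 4 h replicate 4 lay at -58.4 on the first and at -173.2 on the second component, which held 16.0% of the variance. It had a total of 4308976 counts, and its log2 CPM correlated with the other libraries of its group at r = 0.8318 at most across genes, while the lowest r of any other pair within a group was 0.9818 (genes are not independent replicates). The ribosomal precursor Rn45s took 0.0109% of its counts, against 0.982% to 1.09% in the other 3 libraries of the group and 0.386% to 2.73% in the remaining libraries of all groups. Its TMM factor was 0.782, and those of the other libraries lay between 0.909 and 1.105. Its log2 ratio to the rest of its group fell with the GC content of the gene, from a median of 0.77 below 35% GC (28 genes) to -1.77 above 60% GC (495 genes). The library was kept in all main results, and values without it are given where it changed them most.

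**Figure D1:**
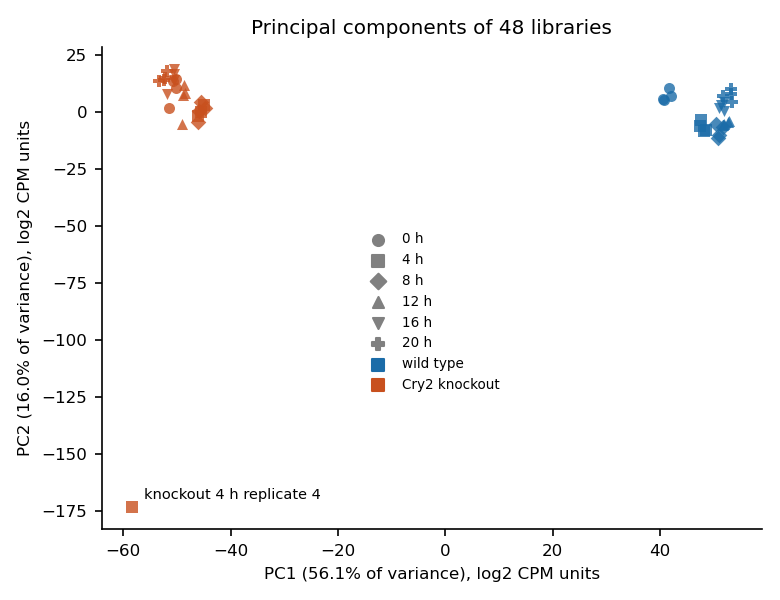
First (x axis, 56.1% of variance) and second (y axis, 16.0% of variance) principal component of log2 CPM for the 48 libraries, with WT and Cry2 knockout in separate colours and a marker shape per time. WT and knockout libraries lie on opposite sides of the first component, and knockout 4 h replicate 4 lies at -173.2 on the second.

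**Figure D2:**
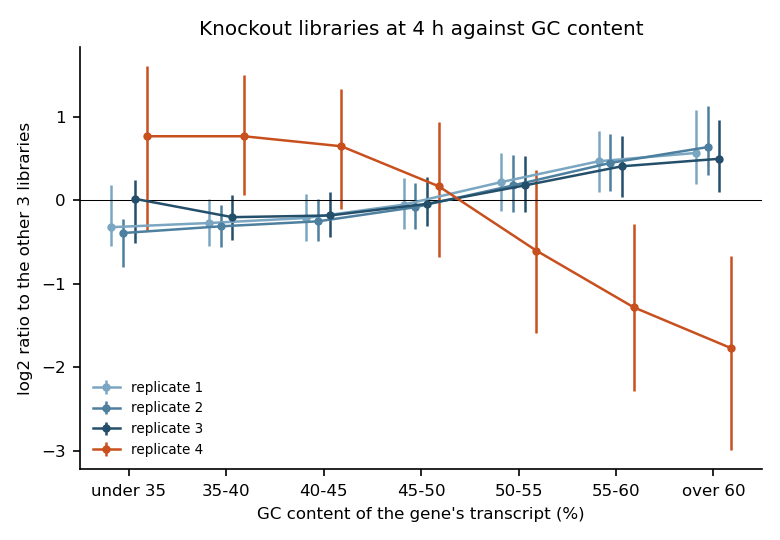
Median log2 ratio of each knockout 4 h library to the other 3 libraries of its group (y axis, bars from the lower to the upper quartile over genes) by GC content of the gene's transcript in percent (x axis). Replicate 4 goes from 0.77 below 35% GC to -1.77 above 60% GC, and the ratios of the others, which hold it in their denominator, mirror it.

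Whether the labels matched the genotype was first checked on Cry2 itself (mm10 chromosome 2, 92403646 to 92434085). Cry2 stood at 17.4 ± 4.0 CPM in WT (SD over all 6 times, n = 24, range 11.1 to 28.6). In KO it stood at 6.28 ± 2.4 CPM (n = 24, range 2.38 to 10.4). Each of the 24 KO libraries lay below the lowest WT library of its time. WT means were 18.3 ± 1.2, 21.4 ± 5.2, 19.9 ± 2.4, 17.1 ± 2.6, 15 ± 2.5 and 12.5 ± 1.6 CPM from 0 to 20 h (n = 4 each). KO means were 7.46 ± 1.3, 7.09 ± 3.3, 8.81 ± 1.4, 6.58 ± 1.7, 3.69 ± 1.1 and 4.04 ± 0.63 CPM. Averaged over times, Cry2 fell by 1.51 on the log2 scale (SE 0.09, adjusted p = 6.8e-20). The ratio of the mean CPM values left 36.1% of the WT level in KO. Counts over the whole gene do not show which exons gave the remaining reads.

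The next question was whether the mRNA of Myc (chromosome 15, 61985341 to 61990361) differed between the genotypes. Myc rose from 55.1 ± 18 CPM in WT to 124 ± 40 CPM in KO (n = 24 each), a 2.25-fold difference (log2 1.17, SE 0.04, adjusted p = 4.2e-28), and all 24 KO libraries lay above the highest WT library of their time. The log2 difference was 1.23, 1.10, 1.2, 1.19, 1.19 and 1.12 from 0 to 20 h. Myc was higher early and lower late in both genotypes. It went from 79.5 ± 6.8 CPM at 4 h to 33.2 ± 3.0 at 20 h in WT and from 175 ± 9.9 CPM at 8 h to 71.9 ± 2.0 at 20 h in KO (n = 4 each). The fitted 24-h amplitude was 0.64 in each genotype, with peaks at 6.7 h (WT) and 6.8 h (KO). Neither the interaction with time (adjusted p = 0.97) nor the difference of rhythms (adjusted p = 0.97) passed. Mycn, a paralog of Myc, had 1 count in the 24 WT libraries and 595 in the 24 KO libraries (ratio 528, 95% interval 94.5 to 20905). Of the 12 genes of the MYC network, Mxd3 rose (log2 1.12), and Mxd4 (-0.83), Mxd1 (-0.68), Mycl (-0.31), Mlx (-0.22) and Max (-0.19) fell in KO; Mycl and Mlx did not pass when log2 RPKM was tested, nor Max without replicate 1, 2 or 3.

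**Figure D3:**
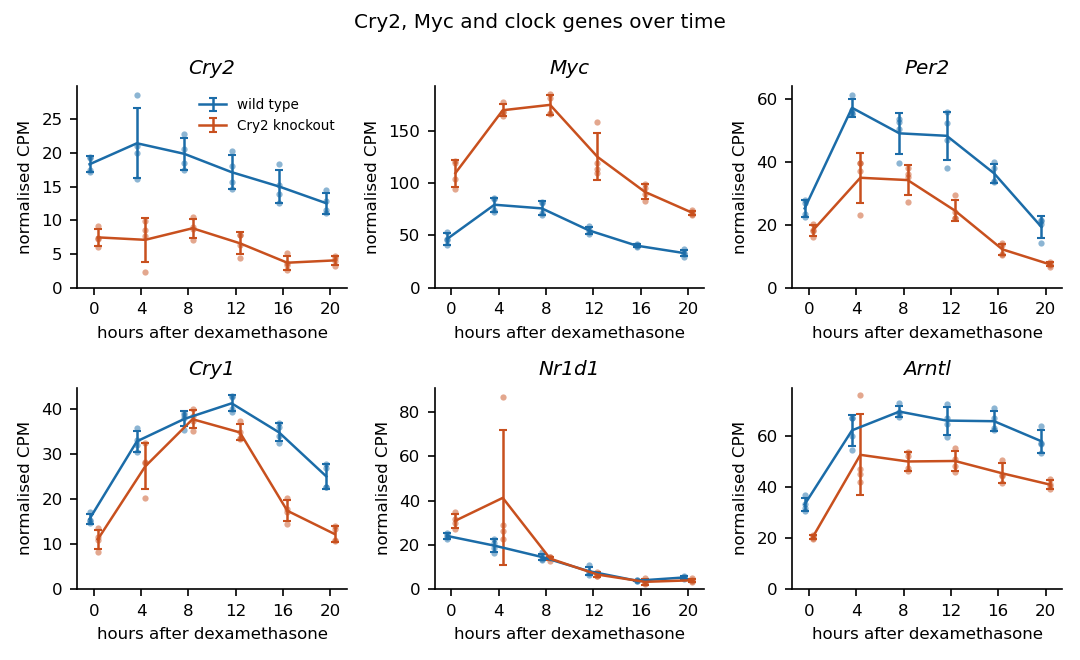
Normalised CPM (y axis) of Cry2, Myc, Per2, Cry1, Nr1d1 and Arntl against hours after dexamethasone (x axis) in WT and Cry2 knockout, with a point per library and lines through means with SD bars (n = 4). Cry2 is lower and Myc higher in knockout at every time, and knockout 4 h replicate 4 gives the high Nr1d1 point of 86.8 CPM.

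Which genes and processes differed between the genotypes was asked with the mean over the 6 times. Genes of DNA replication and mitosis were higher in KO compared to WT. All 28 measured S phase genes rose (median log2 1.64, camera adjusted p = 4.8e-15). They included Rrm2 (91.4 ± 21 to 269 ± 39 CPM, log2 1.58), Mcm6 (1.66) and Mcm7 (1.68). All 27 mitotic genes rose too (median 1.44, adjusted p = 3.7e-15), with Bub1b at 2.06 and Ccna2 at 1.38. Of 59 MYC target genes, 50 rose and 3 fell (50 and 3 adjusted over the list alone; median 0.42, adjusted p = 4.6e-07). Mcm5 (1.76), Mcm4 (1.72) and Plk1 (1.55) rose, and Ipo4 (-0.30), Tfb2m (-0.23) and Ldha (-0.08) fell. None of these last genes fell past the threshold when log2 RPKM was tested, and Ldha then stood at 0.03. Ldha also missed it without KO 4 h replicate 4 (-0.06, adjusted p = 0.051). Of the MYC targets, 5 members belong to another list as well. Cholesterol synthesis rose with 18 of 22 genes higher and 2 lower (19 and 2 adjusted over the list alone; median 0.49, adjusted p = 3.2e-05), led by Acat2 (1.29), Fdft1 (0.73) and Cyp51 (0.70). All 20 replication-dependent histone genes were higher (median 1.55, adjusted p = 6e-05), with Hist1h1a at 2.89 and Hist1h1b at 2.07. The list did not pass with an estimated correlation (adjusted p = 0.5). Reads of near-identical histone genes could be shared.

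Glucocorticoid targets and the extracellular matrix were lower in KO. Of 27 glucocorticoid targets, 21 fell and 3 rose (21 and 3 adjusted over the list alone; median -1.12, camera adjusted p = 9.4e-08). Pdk4 fell from 257 ± 49 to 37.7 ± 9.1 CPM (log2 -2.77). Mt1 (-2.51) and Ampd3 (-1.64) fell too, while Angptl4 (0.81) and Glul (0.44) rose. Of 29 matrix genes, 26 fell and 3 rose (median -0.87, adjusted p = 3.9e-10). These falls included Eln (193 ± 59 to 13.1 ± 4.9 CPM, log2 -3.90), Thbs2 (-2.04) and Sparc (5227 ± 397 to 2594 ± 107 CPM, log2 -1.01). Fbln1 (2.08), Col6a1 (0.71) and Vcan (0.67) rose. Glycolytic genes fell in 13 of 17 cases, with Pfkp (-1.07), Hk1 (-0.82) and Pfkl (-0.66), and Pfkm rose (0.39; median -0.23, adjusted p = 0.01, and adjusted p = 0.35 with an estimated correlation). All 4 measured markers of fat fell, with Fabp4 at -4.45, Pparg at -1.44 and Cebpa at -0.64 (median -1.35, adjusted p = 0.035). The list did not pass with an estimated correlation (adjusted p = 0.058) or without KO 4 h replicate 4 (adjusted p = 0.08). With an estimated correlation the lists of S phase (1.5e-09), MYC targets (0.00045), glucocorticoid targets (0.0017), mitosis (0.003), cholesterol synthesis (0.0087) and matrix (0.0087) still passed. The matrix list then stood at 0.068 without KO 4 h replicate 4.

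**Figure D4:**
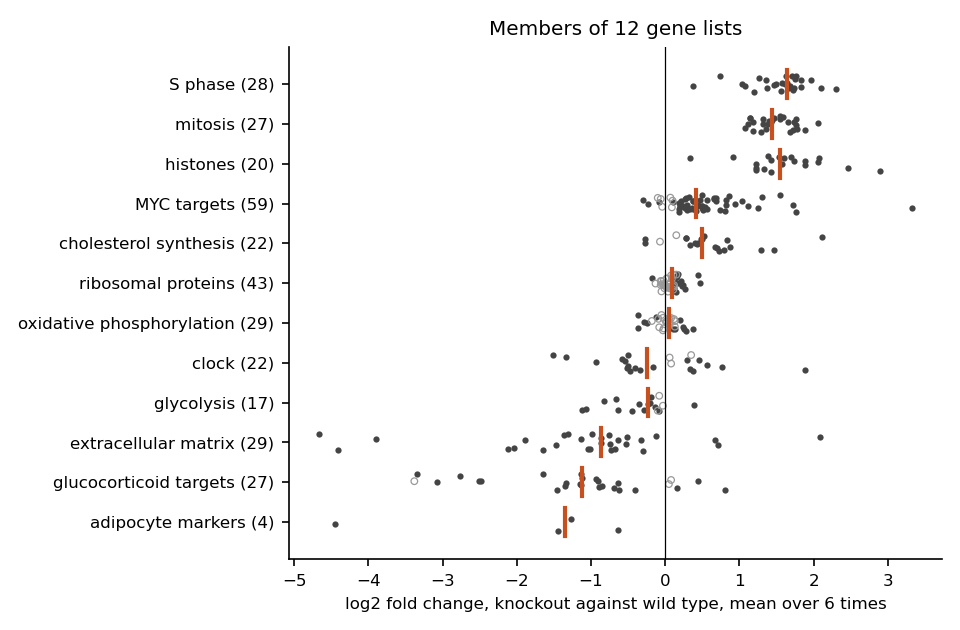
Log2 fold change of knockout against WT, averaged over 6 times (x axis), for each member (points) of 12 gene lists (y axis, number of measured members in brackets); filled points passed an adjusted p of 0.05 and bars are medians. Medians run from 1.64 for S phase genes to -1.35 for markers of fat.

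Across all tested genes the 2 genotypes differed widely. Of 11743 genes, 8876 (75.6%) differed in the mean over times, 4471 higher and 4405 lower in KO, and 1161 of the higher and 826 of the lower genes differed at least 2-fold. With limma on log2(RPKM + 1) the split of 8204 genes was 4973 higher and 3231 lower. The developmental transcription factors Pax8 (chromosome 2, 24420551 to 24475599; 0.0629 to 67.1 CPM, log2 9.84) and Zic1 (chromosome 9, 91358058 to 91365768; 0.0692 to 38.8 CPM, log2 9.14) were among the genes of largest rise. Others were Zic2 (8.92), Vit (0.409 ± 0.33 to 207 ± 27 CPM, log2 9.18), Pcp4l1 (8.55) and Crmp1 (8.54). Rprl3, a multi-copy RNA gene whose reads are uncertain, rose by 11.03. Tmem132e had 0 counts in WT and 2064 in KO, at least 611-fold higher over the group. Fndc3c1 (3 to 2127 counts, ratio 630, 95% interval 215 to 3056) and U90926 (3 to 2088 counts, ratio 618, 211 to 3000) were also nearly absent from WT. The largest falls were in Pax1 (chromosome 2, 147361930 to 147375049; 16.7 to 0.0872 CPM, log2 -8.80), the bone gene Sost (27.6 to 0.0692 CPM, -8.40), Hoxc8 (chromosome 15, 102990539 to 102994275; 52.3 to 0.401 CPM, -7.16) and Itgbl1 (-7.08). Hoxa9 (chromosome 6, 52223097 to 52227370; 8.56 to 0.147 CPM, -6.89) followed, with Tnni3k (-6.75), Cd59a (-6.60), Efemp1 (-6.46), Ndufa4l2 (-6.28) and Eng (chromosome 2, 32646595 to 32682669; 77.6 ± 4.7 to 1.01 ± 0.44 CPM, -6.24, SE 0.07, adjusted p = 6.4e-45). Hoxa9 overlaps a neighbouring gene, so its reads are uncertain. Most of the mean KO level of Pax1 and of Hoxa9 lay in KO 4 h replicate 4 (1.784 and 2.676 CPM), and the levels of the other KO libraries were lower.

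Genes that mark position along the embryo went in both directions. Of 26 measured positional genes, Pitx2 (2.55), Lhx9 (1.19) and Hoxb4 (0.78) were among 9 that rose, and Hoxc8 (-7.16), Hoxc6 (-5.11) and Hoxc5 (-4.56) among 14 that fell. The overlap of Hoxc5 and Hoxc6 leaves their reads uncertain. The list as a whole did not pass (camera adjusted p = 0.059).

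**Figure D5:**
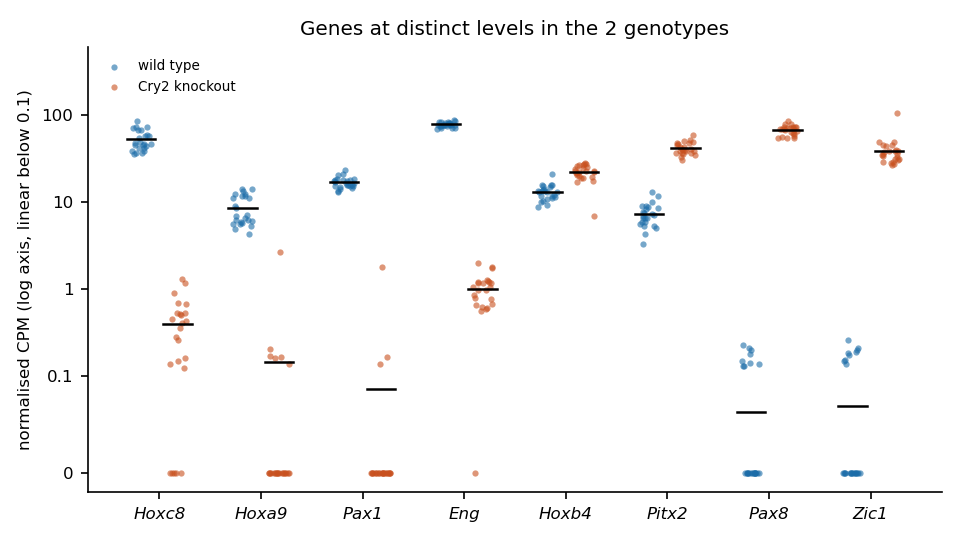
Normalised CPM per library (y axis, log axis that is linear below 0.1; bars are means over 24 libraries) of Hoxc8, Hoxa9, Pax1, Eng, Hoxb4, Pitx2, Pax8 and Zic1 (x axis) in WT and Cry2 knockout. Eng stands at 77.6 CPM in WT and 1.01 in knockout, and Pax8 at 0.0629 and 67.1.

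Further lists held changes in both directions and did not pass camera in the mean over times. For the p53 pathway, 8 of 24 genes rose and 10 fell (adjusted p = 0.99; median -0.08, mean 0.27), from Perp (5.67), Gtse1 (1.41) and Plk2 (1.28) to Pmaip1 (-1.84) and Fas (-1.22). Stress-response genes rose in 6 and fell in 13 of 23 cases (adjusted p = 0.24), with Phgdh (0.82) and Psat1 (0.45) higher and Vldlr (-1.60), Trib3 (-1.52) and Ddit3 (-1.45) lower. Ribosomal protein genes moved little, 16 of 43 higher and 1 lower (15 and 0 adjusted over the list alone; adjusted p = 0.42), with Rpl37 at 0.47 and Rpl6 at 0.14, and their many gene copies make single values uncertain. For the respiratory chain 7 of 29 genes rose and 6 fell (6 and 5 adjusted over the list alone; adjusted p = 1), such as Atp5a1 (0.13) and Sdhc (-0.36). These counts moved when KO 4 h replicate 4 was left out, to 11 and 8 for the respiratory chain and to 22 and 3 for ribosomal protein genes. Contractile genes rose in 6 and fell in 10 of 20 cases (adjusted p = 0.67), with Actg2 (1.07) and Cnn1 (0.56) against Serpine1 (-0.78) and Ctgf (-0.72). Immediate early genes rose in 9 and fell in 12 of 23 cases (adjusted p = 0.44; median -0.14, mean 0.02), with Arc (1.92) and Egr3 (1.87) against Nr4a1 (-0.97). Interferon genes rose in 4 and fell in 6 of 11 cases (adjusted p = 1; median -0.24, mean 0.14), with Gbp2 (2.56) against Ifi44 (-2.26) and Stat2 (-0.59). Inflammatory genes rose in 4 and fell in 4 of 11 cases (adjusted p = 0.84), with Il1rl1 (3.68) and Tnfaip3 (1.53) against Vcam1 (-1.98) and Csf1 (-1.48). The MYC network went 3 up and 5 down of 12 (adjusted p = 1; median -0.07, mean 0.58). For the lists of this paragraph with all 48 libraries, counts adjusted over the list alone were the same where none is given.

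Whether the difference between the genotypes held at each time was asked next. Pax8, Rprl3, Zic1, Zic2, Vit, Fndc3c1, Tmem132e and Adamts9 were the genes of largest rise at 1 or more times, and Pax1, Sost, Hoxc8, Hoxa9, Itgbl1, Cd59a and Tnni3k those of largest fall. The numbers of genes higher and lower in KO were 2494 and 2543 at 0 h, 3433 and 3048 at 4 h, 2724 and 2780 at 8 h, 2813 and 2872 at 12 h, 2818 and 2831 at 16 h, and 2956 and 3079 at 20 h. At all 6 times and in 1 direction, 3094 genes passed, and 7221 of the genes that differed in the mean over times had 1 sign at all 6 times. At 4 h the numbers were 3221 higher and 3477 lower without KO 4 h replicate 4, so the excess of higher genes there rested on that library. With the 8 libraries of 4 h alone, 2176 genes passed at that time.

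Transcripts after dexamethasone were compared across the 6 times within each genotype. Nr4a1, Egr1, Egr3, Atf3 and Errfi1 were among the 10 genes of smallest p in both. Nr4a1 fell from 302 ± 21 CPM at 0 h to 19.3 ± 1.7 at 20 h in WT (log2 range 3.97) and ranged over 4.39 in KO. Egr1 (4.92 in WT, 3.74 in KO), Egr3 (5.99 and 4.91), Atf3 (6.41 and 5.36) and Errfi1 (2.13 and 2.39) changed in both genotypes too. Adamts5 (2.14) and Jun (2.49) joined them in WT. In KO they were joined by Ptx3 (5.13; 1.46 CPM at 4 h and 52.2 ± 2.9 at 20 h), Gas7 (3.56) and Npr3 (3.15). In WT 4602 genes changed across times and in KO 6007. Without KO 4 h replicate 4, which shares the fit with the WT libraries, the numbers were 7293 in WT and 7078 in KO, so their order turned. Without the 0 h libraries the WT number was 3058.

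Fitted 24-h rhythms passed in 4856 genes in WT and 5634 in KO, and in 7021 and 6595 without KO 4 h replicate 4, so the order turned here too. The cell adhesion gene Cd44 led in WT (amplitude 0.75, peak at 7.8 h) and was among the first 10 in KO (amplitude 0.62). Gjb2 (1.86), Sdc4 (1.16), Gja1 (0.98), Timp3 (0.93) and Tenm3 (0.93) followed in WT. In KO the genes of smallest p included Ptx3 (2.28, peak at 19.0 h), Npr3 (1.45), Brinp1 (1.29), Lrrc17 (1.19) and Egln3 (0.96). The sampled 20 h hold less than 1 period, so genes that drifted after 0 h are among those counted.

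The clock itself was asked about through its fixed list. Averaged over times, 7 of the 22 measured clock genes were higher and 12 lower in KO (7 and 12 adjusted over the list alone; camera adjusted p = 0.44). Per2 (-0.93), Clock (-0.51), Cry1 (-0.50), Fbxl3 (-0.50), Arntl (-0.47) and Per1 (-0.40) fell, as did Rora (-1.34) and Usp2 (-0.58), while Timeless (1.89), Csnk1e (0.76), Bhlhe40 (0.57), Nr1d2 (0.45) and Nfil3 (0.34) rose. Nr1d1 (0.06, adjusted p = 0.62), Per3 (0.08, adjusted p = 0.66) and Dbp (0.35, adjusted p = 0.15) did not pass. Clock genes with E-box or D-box promoters, 13 of them measured and all also held by another list, went 4 up and 6 down (camera adjusted p = 0.84; median 0.06, mean -0.09). That median was -0.03 without KO 4 h replicate 4. Across times 19 of 22 clock genes changed in WT (21 adjusted over the list alone) and 19 in KO (19), and 24-h rhythms passed in 18 (19) and 19 (20). Nr1d1 and Nr1d2 had amplitudes of 1.29 and 1.42 in WT and 1.91 and 1.56 in KO with peaks between 3.0 and 3.6 h. The KO mean of Nr1d1 at 4 h (41.2 ± 31 CPM) held 86.8 CPM in replicate 4, against 22.6 to 29 in the rest of its group. Without that library the log2 difference of Nr1d1 at 4 h was 0.39 in place of 1.01, so its KO amplitude may depend on it. Arntl had amplitudes of 0.36 in WT and 0.41 in KO with peaks at 11.4 and 10.6 h. In KO 4 h replicate 4 Arntl stood at 76.4 CPM, against 42.2 to 47.3 in the rest of its group. The KO fit of Arntl may depend on that library too. The WT rhythm of Arntl did not pass without the 0 h libraries (adjusted p = 0.14), nor the KO rhythm of Clock without KO 4 h replicate 4 (adjusted p = 0.093).

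Whether time courses differed between the genotypes was tested directly. Cry1 peaked at 41.3 ± 1.8 CPM at 12 h in WT and at 37.8 ± 2.0 at 8 h in KO (n = 4 each). Its fitted amplitude was 0.57 with a peak at 11 h in WT and 0.97 with a peak at 9.1 h in KO (adjusted p for the difference of rhythms 0.00017). Per2 had an amplitude of 0.72 in WT and 1.08 in KO (peaks 8.4 and 6.9 h, adjusted p = 0.007), and Per1 0.22 and 0.45 (peaks 5.5 and 3.0 h, adjusted p = 0.0044). Both missed the threshold without replicate 2 or 3 (adjusted p of 0.061 to 0.089), and Per1 also without the 0 h libraries (adjusted p = 0.09). In KO 4 h replicate 4 Per2 stood at 23.2 CPM, against 37.2 to 39.7 in the rest of its group. The KO amplitude of Per2 may therefore depend on that library. For Nr1d1 the difference of rhythms did not pass (adjusted p = 0.14), nor for Arntl (0.88) or Nr1d2 (0.89). Of the clock list 6 genes differed in rhythm (6 adjusted over the list alone) and 9 in the interaction with time (11), and of the MYC network 3 (3) and 5 (5).

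Of the 10 genes of smallest p in the difference of rhythms, Bcat1, Asns, Psph, Gpt2 and Slc6a9 had larger amplitudes in KO. Bcat1 went from an amplitude of 0.11 in WT to 0.72 in KO, with 150 ± 6.5 CPM at 8 h and 61.7 ± 5.3 at 16 h (adjusted p for the difference 6e-11). Asns went from 0.06 to 0.75 (9.6e-10), Psph from 0.27 to 0.80 (4.7e-10), Gpt2 from 0.22 to 0.76 (5.5e-10) and Slc6a9 from 0.55 to 0.96 (5.6e-09). Fitted peaks went from 21.5 h in WT to 6.1 h in KO for Psph, from 22.3 to 5.1 h for Gpt2 and from 21.5 to 5.1 h for Slc6a9. Bcat1 and Asns, whose WT rhythms did not pass, peaked at 6.7 and 6.6 h in KO. Peaks also differed for Npr3 (0.9 h in WT and 20.2 h in KO, with amplitudes of 1.06 and 1.45), Pcdh9 (3.8 and 16.3 h) and Haus8 (7.6 and 22.5 h). In the interaction, Cemip fell from 141 CPM at 0 h to 19.3 at 16 h in WT and from 248 at 0 h to 82.1 at 8 h in KO (adjusted p = 1.4e-18). Arhgap10 rose from 62.6 CPM at 0 h to 176 at 8 h in WT against a KO range of 77.4 to 88.2 (adjusted p = 2.4e-17). Adcy5 and Crispld2 were among the 10 of smallest p. The interaction passed in 1567 genes (3130 without KO 4 h replicate 4, 1016 without the 0 h libraries) and the difference of rhythms in 1294 (2585 without KO 4 h replicate 4).

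The early change after dexamethasone was asked for with 4 h against 0 h in each genotype. No untreated group was sampled at 4 h, so effects of the drug, of handling and of time cannot be told apart. In WT, Egr1 stood at 605 CPM at 0 h and 19.9 at 20 h, so a fall from 0 h need not be a response to the drug. Known glucocorticoid targets rose in WT, 16 of 27 higher and 4 lower (17 and 5 adjusted over the list alone; camera adjusted p = 2.7e-07). Fkbp5 (2.61) and Ampd3 (1.62) went up and Rgs2 (-1.68), Cebpb (-0.99) and Nfkbia (-0.98) down. In KO Fkbp5 (1.94) and Ampd3 (1.11) rose too. There 9 of 27 targets rose and 5 fell (10 and 6 adjusted over the list alone), but the list did not pass (adjusted p = 0.24, and 0.14 without KO 4 h replicate 4). The difference between the genotypes in list responses was not tested. Immediate early genes fell in both, 14 of 23 lower and 2 higher in WT (14 and 3 adjusted over the list alone; adjusted p = 4.4e-10) and 17 and 2 in KO (18 and 2; adjusted p = 1.1e-09). Atf3 stood at -3.92 in WT and -2.25 in KO and Egr3 at -3.20 and -2.55. S phase genes fell in 15 of 28 cases in WT (17 adjusted over the list alone; adjusted p = 2.6e-08; Mcm3 -0.75) and in 17 in KO (18; adjusted p = 1.3e-06; Cdc6 -1.26), with none higher in either. Cholesterol synthesis rose in WT, 11 of 22 higher and 1 lower (13 and 1 adjusted over the list alone; adjusted p = 4.4e-08; Msmo1 0.94, Ldlr 0.86). It rose in KO with 8 higher and 1 lower (adjusted p = 0.038, and adjusted p = 0.29 with an estimated correlation), and with 13 higher and 1 lower without KO 4 h replicate 4. MYC targets passed in KO with 25 of 59 higher and 3 lower (26 and 4 adjusted over the list alone; adjusted p = 0.0038; 30 higher and 6 lower without KO 4 h replicate 4; Hk2 1.09, Nop2 0.64) and not in WT (adjusted p = 0.18). Myc itself rose by 0.76 in WT and 0.63 in KO.

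Further lists passed in WT at 4 h against 0 h. Contractile genes rose, 6 of 20 higher and 0 lower (adjusted p = 0.01), with Itga5 at 1.49 and Serpine1 at 0.82. Positional genes fell, 9 of 26 lower and 1 higher (12 and 2 adjusted over the list alone; adjusted p = 0.037), with Hoxc8 at -0.81 and Hoxb2 at -0.55. Mitotic genes (7 of 27 lower, 9 adjusted over the list alone; Ccnb2 -0.60; adjusted p = 0.0011, and adjusted p = 0.32 with an estimated correlation) passed only with the preset correlation. Matrix genes (8 of 29 higher; Postn 0.89; adjusted p = 0.046, and adjusted p = 0.43 with an estimated correlation) and stress-response genes (1 of 23 higher, 3 lower; adjusted p = 0.039, and adjusted p = 0.38 with an estimated correlation) behaved alike. So did histones in WT (4 of 20 lower; adjusted p = 0.036, and adjusted p = 0.62 with an estimated correlation) and in KO (9 lower, 11 adjusted over the list alone; adjusted p = 3.5e-05, and adjusted p = 0.61 with an estimated correlation). In KO 12 stress-response genes rose and 5 fell (13 and 5 adjusted over the list alone, camera adjusted p = 0.1), with Trib3 at 2.03, Asns at 0.89 and Atf4 at 0.53. The list passed only without KO 4 h replicate 4 (13 higher and 3 lower, adjusted p = 0.00016). Without that library interferon genes passed too (adjusted p = 0.017, and adjusted p = 0.031 with an estimated correlation). Contractile (adjusted p = 0.0013, and adjusted p = 0.11 with an estimated correlation) and matrix genes (adjusted p = 0.039, and adjusted p = 0.67 with an estimated correlation) then passed only with the preset correlation.

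Single genes of largest change at 4 h included Cdh6 (5.35), Notch4 (3.34), Gas7 (3.22), Ccbe1 (2.93) and Crispld2 (2.47) among those that rose in WT, and Palmd (-2.95), Fos (-2.85) and Rgs4 (-2.47) among those that fell. In KO Gas7 (3.56) and Ccbe1 (2.82) rose and Ptx3 (-3.46), Palmd (-2.87, and -4.35 without KO 4 h replicate 4) and Arc (-2.41) fell. Several large KO values rested on replicate 4: Pnp2 (4.28, and 0.45 without that library), Pax1 (4.06 and 1.85), Hoxa9 (2.98 and 0.25) and Ppig (2.52 and -0.24) did not pass without it. In WT 1345 genes rose and 1102 fell, 2447 in all (4174 without KO 4 h replicate 4), and in KO 2395 rose and 1705 fell, 4100 in all. Without KO 4 h replicate 4 the KO numbers were 1880 and 1855, 3735 in all, of which 2488 were among the 4100. Neither the larger KO number nor its tilt to higher genes held without that library. Genes higher in both numbered 808, where independent lists would share 274, and genes lower in both 643, against 160. Log2 changes correlated at r = 0.52 across genes, which are not independent replicates. Without KO 4 h replicate 4, 1273 genes were higher in both (367 for independent lists), 995 were lower in both (292), and r was 0.60.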

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

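The tests of E-box clock genes, the 3 tests of KO 4 h replicate 4 and the counts of other splits of the libraries, except that for KO against WT averaged over times, were chosen only after the result was seen.

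KO 4 h replicate 4 lay far from the other 3 libraries of its group in 4 of 10 measures. The gap to the nearest library exceeded Dixon's 95% critical value in these. No library of another group did so in any of the 10 measures, 120 groups of values in all. Chance gives about 1 in 20, more than 4 of 120, so the evidence lies in the gathering of all 4 in this library and not in their number. Rn45s took 0.0109% of its counts, against 0.982% to 1.09% in the others. Per2 stood at 23.2 CPM (37.2 to 39.7 in the others), Nr1d1 at 86.8 CPM (22.6 to 29) and Arntl at 76.4 CPM (42.2 to 47.3).

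Time courses that differed between the genotypes in a test of the difference itself stood out as well. The interaction of genotype and time passed in 1567 genes. The swing of the KO against WT log2 difference over the 6 times was 3.89 for Adcy5, 2.92 for Npr3, 2.80 for Cemip, 2.73 for Crispld2, 2.52 for Cyp26b1, 1.87 for Sdc4, 1.78 for Gjb2, 1.53 for F3, 1.51 for Arhgap10 and 1.42 for Adamts5. Among clock genes it was 1.43 for Nr1d1 (0.81 without KO 4 h replicate 4), 1.34 for Ciart, 1.11 for Per2, 1.09 for Tef, 1.04 for Cry1, 1.01 for Rora, 0.97 for Bhlhe40, 0.72 for Wee1 and 0.67 for Per1. In the MYC network it was 1.67 for Mxd3, 1.21 for Mxi1, 1.0 for Max (0.54 without KO 4 h replicate 4), 0.58 for Mxd4 and 0.39 for Mlxip. Without the 0 h libraries 1016 genes passed, and Per1 (adjusted p = 0.07), Rora (0.051), Tef (0.061), Ciart (0.072), Mxd4 (0.15), Mxi1 (0.07) and Mlxip (0.19) no longer did. Without KO 4 h replicate 4 the interaction passed in 3130 genes and the difference of rhythms in 2585. The rhythms differed in 1294 genes, with an amplitude of the difference of 1.5 for Npr3, 1.29 for Slc6a9, 1.06 for Hs3st3b1, 0.99 for Psph, 0.96 for Pcdh9, 0.84 for Gpt2, 0.78 for Asns, 0.75 for Haus8, 0.66 for Bcat1 and 0.48 for Itgb3.

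Other splits of the same libraries were used to ask whether chance could give as many genes. For KO against WT averaged over times, 1 of 100 splits, the real one, gave 8876 genes, and the highest other gave 2736. At single times, 1 of 35 splits, the real one, gave as many: 5037 at 0 h (highest other 1222), 6481 at 4 h (4355), 5504 at 8 h (377), 5685 at 12 h (1449), 5649 at 16 h (842) and 6035 at 20 h (407). Across times 1 of 60 splits gave as many in each case: 4602 in WT (14), 6007 in KO (991), 1567 for the interaction (1), 4856 for the WT rhythm (11), 5634 for the KO rhythm (210) and 1294 for the difference of rhythms (2). For 4 h against 0 h, 1 of 35 splits gave 2447 genes in WT (78) and 1 of 35 gave 4100 in KO (3178). A random assignment of single libraries did not reach these counts of genes. Splits that mix distinct groups widen the spread within groups, which leaves them few calls. A chance difference between embryos or lines was not excluded, since libraries of a group may be technical and no split tests it. The median of the other splits was 0 in all of these comparisons except KO against WT at 4 h (883.5), KO across times (239) and KO 4 h against 0 h (1247), which all hold KO 4 h replicate 4. In these, the distance of that library from the rest may give calls under splits unrelated to the comparison.

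Counts of gene lists past camera were weaker evidence. The adjusted p of MYC targets (4.6e-07) was matched in 3 of 100 splits, the real one included, and the smallest other was 5.2e-08. That share does not exclude chance, since this was 1 of several split tests chosen after the result was seen. The median of the other splits was 0.011, so most of them passed as well and camera's p for this list overstates the evidence. For the 8 other lists past camera in KO against WT, 10 of 100 splits gave as many (highest other 9), so chance was not excluded. In WT at 4 h against 0 h, 1 of 35 splits, the real one, gave 10 lists (highest other 9). This is the smallest share that 35 splits can give, and the margin was narrow. In KO, 5 of 35 splits gave 5 lists or more (highest other 7), and chance was not excluded.

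Most tested genes differed between KO and WT, from Hox and Pax genes to the cell cycle. Of the genes changed at least 2-fold, 0.81% (16 of 1977 with a position) lay within 10 Mb of Cry2, against 0.56% of tested genes. Only 65 tested genes lie there, so this share had to be small and cannot decide on a chromosome segment of donor strain. Effects of such a segment on genes elsewhere were not tested. GC content was excluded as the main source, since it explained 0.05% of the variance of the log2 differences. Release of E-box clock genes from repression by CRY2 stayed open, since their median was 0.06 (-0.03 without KO 4 h replicate 4) with members in both directions. Lines from different parts or tissues of the embryo may contribute, since positional genes had a median absolute log2 difference of 0.67, at percentile 98.0 of 10000 matched lists (median 0.39), and an effect of Cry2 itself cannot be parted from this by the design.

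KO 4 h replicate 4 stood apart from its group, and a library wholly of the other genotype was excluded. The 22 genes nearly absent from WT stood at a median of 105.5% of their level in the other 3 libraries (lowest 3.5%). An earlier form of this test found 18.2% of 500 genotype genes nearer to the WT mean. Admixture of some WT material was not tested, since the 22 genes would stay near their level under it. Capture of poly(A) RNA, in place of the depletion used for the rest, is consistent with the loss of histone transcripts, which lay -3.81 (SD 2.72, 20 genes) from genes of like GC content and level and -3.61 (SD 2.93) from genes of like GC content and length. So are the low log2 ratios of Rn45s (-6.15), Rpph1 (-5.25) and Rmrp (-4.86), while Malat1 was higher (1.39). GC bias stayed open as a part, since GC content explained r squared = 0.230 of its log2 ratios across genes (r = -0.48), against at most 0.145 in libraries of other groups (KO 0 h replicate 2), and left most of their variance unexplained. No biological explanation was tested, since the labels give this library the same treatment as its group.

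Myc mRNA was 1.17 higher (log2) in KO averaged over times. For gain of a chromosome 15 segment, the 46 genes within 10 Mb of Myc had a median of 0.14 (95% bootstrap interval -0.06 to 0.45). Of these, 39 had a log2 difference under that of Myc. These values argue against a gain of the whole window that raised its genes as much as Myc. A smaller gain or a shorter segment stayed open, since the genes spread in both directions (SD 1.17) by more than the distance of their median from Myc. Scaling was excluded, since Myc stood 1.16 above the mean of 5 housekeeping genes and at 1.19 with DESeq2 size factors. MYC targets had a median of 0.42, above all 10000 lists matched on expression (their median -0.02). A rise of MYC activity with its mRNA would give this. The matched lists were drawn gene by gene and do not keep the correlation between members. Under other splits of the libraries the camera adjusted p of MYC targets had a median of 0.011. S phase (median 1.64) and mitotic genes (1.44) rose as well, so the list cannot tell MYC activity from growth. Whether loss of Cry2, faster growth or another difference between the lines lies behind the higher Myc mRNA and MYC targets remained open, since each is confounded with genotype.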

How the results depend on the processing

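The fits without KO 4 h replicate 4 (apart from KO against WT at 4 h and KO 4 h against 0 h, where leaving out single libraries was planned) and those to replicate numbers 1 and 3 or 2 and 4 were chosen only after the data were seen.

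The difference between the genotypes averaged over times passed in 6971 to 9764 genes under all alternatives run, against 8876. DESeq2 gave 8922 genes, sums over times of 4 against 4 libraries 9031, limma voom with a random effect 8390 (consensus correlation 0.067), numbers 1 and 3 alone 9311 and numbers 2 and 4 alone 6971. On log2(RPKM + 1) 8204 genes passed, of which 60.6% were higher in KO, against 50.4% with counts. The fits to RPKM used no TMM scaling. TMM factors were mostly lower in WT (0.909 in WT 8 h replicate 2) than in KO (1.105 in KO 16 h replicate 1). Whether this made the difference was not tested. Pairs of numbers 1 and 3 lay closer to counting error than other pairs (median chi-square per degree of freedom 1.835 against 4.27, KO 4 h replicate 4 left out). At WT 0 h, WT 20 h and KO 20 h the pair of numbers 2 and 4 lay closer (1.71, 2.23 and 2.25 against 3.98, 2.55 and 2.28). Libraries of numbers 1 and 3 may be less independent than the rest, and p-values over 4 libraries would then be too small. For KO against WT averaged over times, Cry2, Myc and the MYC target list kept direction and side of the threshold under all alternatives run. For the list this carries little weight, since most other splits of the libraries passed camera as well (median adjusted p 0.011).

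Leaving out KO 4 h replicate 4 raised the number of genes across times in WT from 4602 to 7293, for the interaction from 1567 to 3130, for the difference of rhythms from 1294 to 2585 and for WT 4 h against 0 h from 2447 to 4174. Leaving out each replicate number in turn gave 2903 to 6729 genes across times in WT, 743 to 2866 for the interaction, 3237 to 6371 for the WT rhythm (7021 without KO 4 h replicate 4, against 4856), 551 to 2116 for the difference of rhythms and 1460 to 3722 for WT 4 h against 0 h. These fits hold fewer libraries, and those without number 4 also lack the library that stands apart. Single libraries other than KO 4 h replicate 4 moved none of the counts of genes by more than 1.5 times in the 1-library fits run.

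Fits to part of the libraries use another estimate of spread. The 24 libraries of 1 genotype gave 7551 genes across times in WT and 3599 in KO, and 4451 (WT) and 2334 (KO) for 4 h against 0 h. The 8 libraries of 4 h gave 2176 genes between the genotypes at that time. Without the 0 h libraries 3058 genes passed across times in WT and 1016 for the interaction, with fewer libraries and less of the early change.

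Of the lists other than MYC targets, 8 passed for KO against WT, 5 with an estimated correlation and 24 with fry, which does not compare a list with other genes. For 4 h against 0 h, 15 list results passed over both genotypes, 9 with an estimated correlation and 33 with fry.

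Replicate numbers were not taken to pair the libraries, since the labels tie them to nothing shared and the deviations of like numbers did not correlate above 0.1 in every pair (lowest -0.061). They did so in 21 of 24 pairs (median 0.199), and 38 of 48 libraries correlated best with their own number, a hint from the data that numbers share something. With the replicate block 8993 genes passed for KO against WT averaged over times, 5251 at 0 h, 6622 at 4 h, 5719 at 8 h, 5895 at 12 h, 5845 at 16 h and 6241 at 20 h. It gave 4888 across times in WT, 6285 in KO, 1770 for the interaction, 5055 and 5782 for the WT and KO rhythms, 1407 for their difference, and 2614 (WT) and 4312 (KO) for 4 h against 0 h.

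Of 10958 values of named genes under alternatives, 10377 kept their side of the threshold, 463 no longer passed, 105 newly passed and 13 reversed. Direction was compared only for values that passed in the main fit, so changes of sign in the rest are not among the 13. In KO 4 h against 0 h, Bhlhe41 went from 0.75 (adjusted p = 0.083) to -0.43 (0.037) without KO 4 h replicate 4. Ldha in KO against WT stood at 0.03 in each of the 3 fits to log2 RPKM. These used no TMM scaling, and the cause was not tested. The other reversals were in KO 4 h against 0 h. Without each replicate number in turn, Ppig ran from -0.17 to 3.10, Rps3 from -0.62 to 0.05, Rps18 from -0.71 to 0.04, Mdm2 from -0.09 to 0.84, Atp5f1 from -0.09 to 0.62 and Cdkn1b from -0.12 to 0.92, with the change of sign without number 4. Without KO 4 h replicate 4 alone, Ppig stood at -0.24, Mdm2 at -0.06, Atp5f1 at -0.11 and Cdkn1b at -0.14. In the simulation, 52.2% of 1.5-fold changes were recovered at 4 h alone and 97.0% in the mean over times. Its libraries were independent and none stood apart. How far depth and library number limit single times in the data was therefore not shown.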

Other observations

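The lists of cell types and small gene groups were fixed before any value was seen. Of the values that follow, only those without KO 4 h replicate 4 come from a fit chosen later.

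Inhibitors of cyclin-dependent kinases went both ways in KO against WT. Cdkn1b (log2 1.11), Cdkn2d (0.53) and Cdkn2c (0.38) rose, while Cdkn1c (-3.34) and Cdkn2b (-3.23) were among those that fell, 3 and 4 of 7 in all (camera adjusted p = 0.33). Antioxidant genes rose in 5 and fell in 8 of 15 cases (adjusted p = 0.44), with Slc7a11 at 2.02, Hmox1 at -1.26 and Nqo1 at -1.13. Of 9 nuclear RNAs, 6 fell and 1 rose (7 and 2 adjusted over the list alone; adjusted p = 0.077). Without KO 4 h replicate 4, 10 were measured, of which 7 fell and 3 rose. Neat1 (-2.22), Malat1 (-1.38) and Meg3 (-0.71) were lower, and Kcnq1ot1 (0.40) was higher.

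Markers of other cell types were also compared between KO and WT. Cartilage and bone genes rose in 3 and fell in 3 of 7 cases (adjusted p = 0.98), with Comp (1.48) and Spp1 (1.38) against Col10a1 (-2.91) and Acan (-1.62). Of 5 muscle genes, Des (-2.68) and Acta1 (-2.22) fell and none rose (adjusted p = 0.33). Of 3 neural genes, Stmn2 (6.62) and Map2 (0.78) rose (adjusted p = 0.24). Of both endothelial genes measured, Kdr rose (1.23) and Erg fell (-1.29; adjusted p = 1). Lists with 1 measured gene had no list test. Krt19 of epithelium rose from 16.2 ± 5.3 to 43.2 ± 8.3 CPM, Coro1a of blood cells from 0.228 ± 0.2 to 1.06 ± 0.58 CPM, and the sex-linked Xist from 258 ± 38 to 403 ± 86 CPM (SD, n = 24 each). The labels name no cell type other than fibroblasts, and no source of these transcripts was tested.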
